A study of Homo sapiens with 8 samples.

How the data were processed

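Ribosome profiling sequences the mRNA fragments that ribosomes protect from nuclease, so reads report where ribosomes lay. It was applied to 8 libraries in 4 groups of 2, HEK293T cells and transgenic HEK293T cells, each without NAEK or with NAEK at 1 mM. Per the labels' protocols, libraries were made with the TruSeq Ribo Profile kit. Bowtie 1.2.2 and the genome build hg38 are named in the submitters' processing notes. The annotation, the read length filter and the treatment of reads that fit several isoforms are not given in the sources used here. The authors deposited 4 tables, 1 per group, that hold RPKM (reads per length of the region and per total reads of the library) in the coding region, the first extended region and the second extended region of 82586 transcripts, per the file headers. Of these, 65003 were annotated as protein-coding, 17577 as targets of nonsense-mediated decay and 6 as targets of non-stop decay. Both transgenes have entries of their own, a pyrrolysyl-tRNA synthetase (CMV-pylRS-I-P_2512-3801) and a GFP construct (pSD31-GFP39-I-H). Groups and replicates were taken from the table names and column headers as matched to the sample labels.

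How the extended regions were defined is not given in the sources used here. They were read as the stretches after the stop codon of the coding region and after the next stop codon. Region lengths were recovered from the values, and among regions with at least 200 reads the share with a length in whole codons was 93.4% for coding, 91.6% for first extended and 100.0% for second extended regions. Median lengths were 1137, 135 and 103.5 nt.

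Whole reads were recovered from the RPKM. In a library, the values of a region are whole multiples of what 1 read is worth, and the synthetase entry names its own start and end, 1290 nt apart counting both, which fixes the total of each library. Relative to a reference library, what 1 read is worth was the same in coding and first extended regions. With these totals, 100.0% of entries above 0 came out whole in each of the 3 regions within 0.01 reads. Totals ran from 12923243 to 20569590 reads. In simulated RPKM of known reads, the recovery returned 99.96% of coding and 99.1% of first extended reads. All reads of a transcript came back exactly for 97.5% of coding and 90.5% of first extended regions, and for 99.6% and 99.2% of those with at least 10 reads. A recovered length is the shortest that makes all reads whole, so in thin regions lengths and reads can fall short of the true ones. Recovered reads served for depth, shares, minimums and an alternative test, never for the main test. Intervals and floors cover counting error only, since PCR copies are not independent molecules. A floor is 3 reads, and intervals are exact Clopper-Pearson at 95%.

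The design fixed before the data were examined assumed read counts. Because the deposited values are RPKM, edgeR was not used and DESeq2 was not used. In their place, as the same design provides, limma 3.58.1 in R 4.3.3 tested log2(RPKM + 1) with a variance trend, group as the only factor, and all 8 libraries in 1 fit. The 5 contrasts were the NAEK effect in each cell line, the difference between cell lines at each NAEK state, and the interaction, each with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of low values. Coding regions needed a mean of at least 1 RPKM, which left 46156. Extended regions needed a mean of at least 50 coding reads and at least 10 reads in the region over all libraries, which left 7801 first and 3238 second extended regions. These minimums were set once the structure of the tables was known and before any count of changed regions was seen. Tests of single extended regions were not in the fixed design, which named shares of footprints. Labels do not say whether replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical.

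The share of footprints in extended regions was summed per library over the 30505 transcripts with a mean of at least 50 coding reads, leaving the transgenes out, and expressed in percent of their coding reads. Shares were compared by exact two-sided permutation tests, which cannot go below p = 0.333 with 2 libraries against 2. Sets of transcripts were tested with camera in limma, with a preset correlation of 0.01 and with an estimated one. The SE of a set mean is taken over its transcripts, which can share a gene, and does not measure the spread between libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 did the rest.

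The limma step was tested on simulated values for the NAEK contrast in transgenic cells. Among 46156 coding regions it called 69% of 100 simulated 2-fold changes and 100% of 100 simulated 8-fold changes, with 19 false calls beside those. Among 7801 first extended regions it called 3% and 38%, with 10 false calls beside those. In both kinds of region the rate of false calls was above the nominal one. In the simulated contrast without changes it made 0 coding and 2 first extended calls.

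The rule for named transcripts was the largest rises and falls among those past the threshold whose libraries did not overlap. The files used here do not pair transcript IDs with genes, and 0 IDs matched the reference table of names, so at most 2 IDs that rose and 2 that fell are printed per comparison. For the same reason, the fixed gene lists and markers of other cell types could not be run. Stop codons of the transcripts were not used here, so the planned split by stop codon could not be run either. Alternatives tried were other read minimums and none, pseudocounts of 0.1 and 5, upper quartile scaling, a replicate block, fits to the 4 compared libraries, and each library left out in turn. Added after seeing the data were voom on recovered reads, no variance trend, the log2 ratio to the coding region, at least 30 reads in the region, and subsets of transcripts for the shares.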

Results

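HEK293T is a human embryonic kidney line that expresses the SV40 large T antigen. The transgenic cells are HEK293T cells that stably carry the tRNA of a pyrrolysine system. In such a system, a pyrrolysyl-tRNA synthetase charges its tRNA with a supplied amino acid, here NAEK, an azide-bearing lysine derivative, and the charged tRNA decodes the amber stop codon UAG. The series asked where ribosomes lie on mRNAs in both kinds of cell. Ribosome footprints were measured in 4 groups of 2 libraries, HEK293T and transgenic cells without and with 1 mM NAEK. HEK293T libraries held 17261848 and 17630299 reads without NAEK and 20569590 and 16197846 with it. Transgenic libraries held 17381811 and 18367663 reads without NAEK and 17211388 and 12923243 with it. Coding regions took 89.0 to 89.1% of reads, first extended regions 1.29 to 1.48% and second extended regions 1.01 to 1.15%. A floor of 3 reads was at most 2.32e-05% of a library. Across transcripts, which are not independent replicates, log2 coding RPKM correlated with Pearson's r of 0.980 to 0.985 within groups and 0.968 to 0.987 between groups. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 2.68 to 7.49.

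The synthetase and GFP39 transgenes carried dense footprints in transgenic cells and few in HEK293T cells. Synthetase coding density was 5679 ± 200 RPKM (SD, n = 2) in transgenic cells without NAEK and 5590 ± 35.6 RPKM with it, against 10.6 ± 1.13 and 8.45 ± 1.72 RPKM in HEK293T cells. GFP39 coding density was 3713 ± 68.4 RPKM in transgenic cells without NAEK and 6622 ± 506 RPKM with it, against 16.0 ± 8.12 and 8.46 ± 0.445 RPKM in HEK293T cells. Means of the synthetase were 535-fold higher in transgenic cells without NAEK and 661-fold higher with it. By limma, the log2 difference between lines for the synthetase was 8.94 (adjusted p = 1.32e-07) without NAEK and 9.22 (adjusted p = 1.03e-07) with it, and for GFP39 7.86 (adjusted p = 5.39e-05) and 9.45 (adjusted p = 1.26e-05). With NAEK, neither transgene's coding region passed the test in transgenic cells. The synthetase differed by -0.02 (log2, limma adjusted p = 0.994) and GFP39 by 0.83 (SE 0.27, limma adjusted p = 0.791). Under voom, chosen after seeing the data, GFP39's coding region passed with an adjusted p of 0.000193, and over its 13 alternatives adjusted p ran from 0.000193 to 1.0.

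**Figure D1:**
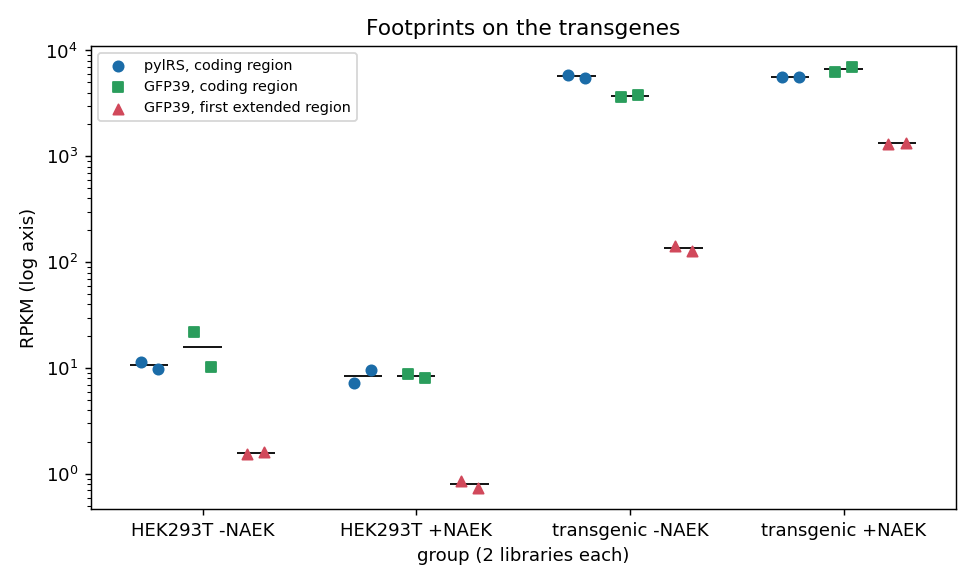
Footprint density (RPKM, log axis) of the synthetase and GFP39 coding regions and the GFP39 first extended region in each of 8 libraries, by group, with a point per library and a line at the mean of 2. The first extended region of GFP39 stood at a mean of 135 RPKM in transgenic cells without NAEK and 1323 RPKM with it.

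NAEK raised footprint density after the stop codon of the GFP39 coding region in transgenic cells. Its coding region came out as 144 nt and its first extended region as 672 nt. Density in the extended region was 135 ± 9.21 RPKM (SD, n = 2) without NAEK and 1323 ± 15.2 RPKM with it, 9.79-fold higher, and in HEK293T cells 1.58 ± 0.037 and 0.802 ± 0.094 RPKM. Relative to coding density it was 3.64 ± 0.311% without and 20.02 ± 1.301% with NAEK in transgenic cells, a 5.50-fold difference (exact permutation p = 0.333, the smallest possible). The second extended region, 126 nt, held 11.8 ± 2.03 and 19.5 ± 5.01 RPKM, a difference that did not pass (limma adjusted p = 0.793), and 0 reads in HEK293T cells. The log2 rise of the first extended region was 3.28 (SE 0.27, limma adjusted p = 0.0223). It passed under 10 of 17 alternatives, with adjusted p from 7.9e-39 to 0.183, and was lost without transgenic -NAEK replicate 1 (0.157), without replicate 2 (0.183) and without transgenic +NAEK replicate 2 (0.059), while the log2 change stayed between 2.45 and 3.35. In HEK293T libraries, which should hold no GFP39, the change was -0.52, on 18 and 19 reads without NAEK and 12 and 8 with it. The interaction of 3.80 (SE 0.38) did not pass (limma adjusted p = 0.114). Under 3 of 20 alternatives it passed, with log2 values from 2.21 to 4.23 over the 20. Since HEK293T cells should lack the gene, the interaction cannot compare how the lines respond.

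First extended regions of endogenous transcripts also gained footprints with NAEK in transgenic cells. Among 7801 regions tested, 125 rose, GFP39 included, and 11 fell. The excess of rises shrank under some alternatives, and under others no region passed. With a pseudocount of 0.1, 12 rose and 9 fell, and without transgenic +NAEK replicate 1, 24 rose and 16 fell. The 124 endogenous regions that rose had a median length of 119.5 nt and, by library, a median density of 20.8 and 22.7% of the coding density with NAEK, a level inflated by choosing the regions for their rise in these libraries. Over all 30505 transcripts with enough coding reads the median was 0 in each library. The 11 that fell had a median length of 12 nt, and 10 of them were at most 30 nt long. Of the regions that rose, 123 lay on protein-coding transcripts, 2.02% of those tested, and 1 on a nonsense-mediated decay transcript, 0.058% of those tested (Fisher's exact two-sided p = 2.4e-12, over transcripts that are not independent). The types started from unlike levels, so these counts do not show that decay transcripts were spared. In transgenic cells, summed first extended reads went from 9.01 to 9.25% of coding reads with NAEK in nonsense-mediated decay transcripts. In protein-coding transcripts they went from 0.542 to 0.619% (exact permutation p = 0.333 for each, the smallest possible). The share of protein-coding transcripts also rose with NAEK in HEK293T cells, from 0.573 to 0.615% (exact permutation p = 0.333). With NAEK, libraries of the lines overlapped in that share (exact permutation p = 0.667). In decay transcripts of HEK293T cells it went from 9.08 to 9.09%, with overlap (exact permutation p = 0.667). ENST00000329421, with a region of 204 nt, went from 3 and 5 reads to 171 and 190 reads, or from 1.09 ± 0.345 to 60.4 ± 16.5 RPKM (SD, n = 2; log2 change 4.86, limma adjusted p = 0.0354). It passed under 12 of 18 alternatives, but not without transgenic -NAEK replicate 1 (adjusted p = 0.179), transgenic -NAEK replicate 2 (0.183) or transgenic +NAEK replicate 2 (0.0642). The other named rise, ENST00000370112, rested on a region of 3 nt with 0 reads in both libraries without NAEK and 1 and 2 reads with it, too few for a fold. The named falls, ENST00000339865 and ENST00000399455, had regions of 6 nt, with 3 and 3 and with 1 and 4 reads without NAEK and 0 reads with it.

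The count of 136 was sensitive. All adjusted p lay between 0.0223 and 0.0498, the regions that rose held a median of 24 reads over 8 libraries, and 98 of the 124 held under 50. It was 0 without either transgenic -NAEK library, 40 without transgenic +NAEK replicate 1, 4 without replicate 2, 0 with no read minimum, 0 when only the 4 libraries compared were fitted, 11 with at least 50 reads in every library of 1 group, 1 for the log2 ratio to the coding region, 21 and 226 with pseudocounts of 0.1 and 5, 76 without a variance trend and 274 under voom. At an unadjusted p under 0.05 there were 972 regions, against 390 from chance.

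A count that does not select on the libraries compared was made after seeing the data. Protein-coding transcripts were chosen on HEK293T libraries alone, with a mean of at least 1000 coding reads and a first extended density under 2% of the coding density, which left 1515 transcripts that can share a gene. With NAEK, 76 of them (5.02%) reached at least 5% of the coding density in both transgenic libraries. Without NAEK, 5 did (0.33%). Per library there were 146 and 148 with NAEK and 39 and 48 without it, and the exact permutation p of 2 libraries against 2 is 0.333 at its smallest. The mirrored choice on transgenic libraries left 1399 transcripts, of which 21 reached 5% in both HEK293T libraries without NAEK and 25 in both with it, or 76 and 77 in single libraries without NAEK and 72 and 90 with it. At least 10% of the coding density was reached in both libraries by 31 of the 1515 transcripts with NAEK and by 0 without it, which allows a share of up to 0.198% for both libraries at once. In single libraries it was reached by 58 and 55 transcripts with NAEK and by 13 and 15 without it, and 20% of the coding density by 1.06 and 1.45% of transcripts with NAEK.

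**Figure D2:**
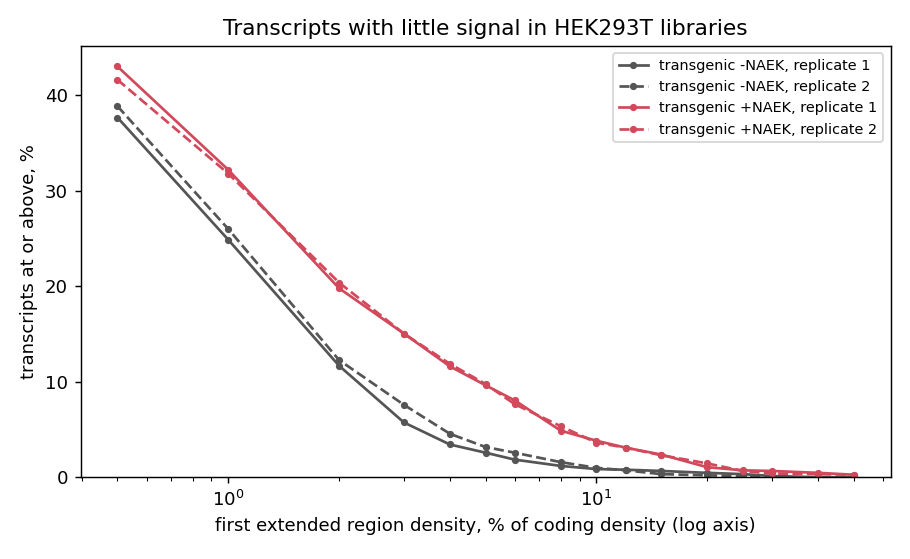
Share of the 1515 transcripts chosen on HEK293T libraries (vertical axis, %) whose first extended density was at or above a given percentage of coding density (horizontal axis, log), with a line per transgenic library. At 5% of the coding density the libraries with NAEK stood at 9.64 and 9.77% of transcripts and those without it at 2.57 and 3.17%.

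Summed over 30505 transcripts without the transgenes, first extended regions held 1.03 ± 0.010% of coding reads (SD, n = 2) in transgenic cells without NAEK and 1.11 ± 0.0036% with it. The difference of 0.0757 percentage points exceeded the spread between replicates, and libraries of the groups did not overlap, which the exact permutation test gives by chance at p = 0.333, the smallest 2 libraries against 2 allow. Second extended regions held 0.728 ± 0.0061% and 0.737 ± 0.0074%, and libraries overlapped (exact permutation p = 0.667). That difference of 0.0092 percentage points was 0.0049 without transgenic -NAEK replicate 1, 0.0145 without transgenic +NAEK replicate 1 and 0.0040 without transgenic +NAEK replicate 2. With the transgenes included, the difference for first extended regions was 0.168 percentage points.

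**Figure D3:**
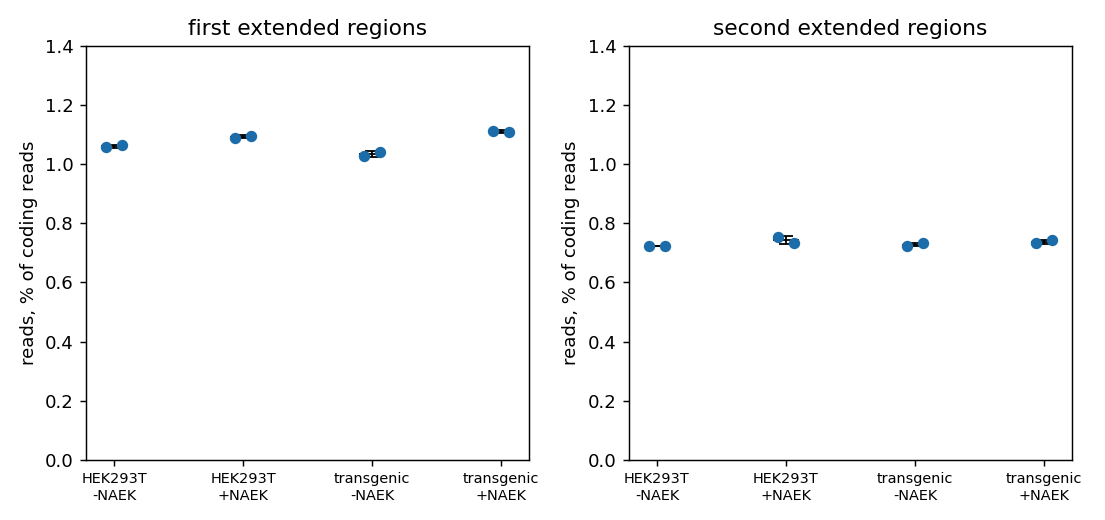
Reads in first (left) and second (right) extended regions as a percentage of coding reads (vertical axes) in 4 groups, with a point per library and the mean and SD of 2 in black. First extended regions ranged from 1.03% in transgenic cells without NAEK to 1.11% with it.

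No coding region passed the test for NAEK in transgenic cells. Of 46156 coding regions, limma called 0. At an unadjusted p under 0.05 there were 2739, against 2308 from chance, and voom called 9. In the second extended regions, 2 of 3238 passed, both on nonsense-mediated decay transcripts with regions of 9 nt. ENST00000496634 went from 0 reads in both libraries to 9 and 5 reads (log2 5.67, limma adjusted p = 0.00161), and ENST00000589468 from 3 and 5 reads to 0 (log2 -4.65, limma adjusted p = 0.0141). These fitted changes depend on the pseudocount. ENST00000496634 stood at 50.5 RPKM in transgenic cells with NAEK, near the 35.1 and 47.6 RPKM of HEK293T cells without and with NAEK. Only transgenic cells without NAEK stood apart there. The count was 1 without transgenic -NAEK replicate 1, 6 without transgenic +NAEK replicate 1, 1 without transgenic +NAEK replicate 2, and 0 when only the 4 libraries compared were fitted and under voom.

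In HEK293T cells, which lack the tRNA transgene, no region of any kind passed the test for NAEK. For coding regions limma called 0 of 46156, with 1392 at an unadjusted p under 0.05 and 1 under voom. For first extended regions it called 0 of 7801, with 284 at an unadjusted p under 0.05 and 2 under voom, and for second extended regions 0 of 3238, with 128 and 0. Changes in first extended regions are not excluded by this. Simulated for the transgenic contrast, 3% of 2-fold and 38% of 8-fold changes there were called. First extended regions held 1.06 ± 0.0048% of coding reads (SD, n = 2) without NAEK and 1.09 ± 0.0042% with it, and libraries did not overlap (exact permutation p = 0.333, the smallest possible). This difference of 0.0316 percentage points was 0.0002 without the 10 transcripts with the most reads in the region. Second extended regions held 0.723 ± 0.0002% without NAEK and 0.743 ± 0.0126% with it, also without overlap (exact permutation p = 0.333, the smallest possible), a difference of 0.0206 percentage points that was 0.0118 without HEK293T +NAEK replicate 1. The GFP39 and synthetase coding regions changed by -0.76 (limma adjusted p = 1) and -0.30 (limma adjusted p = 1) on the log2 scale.

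Without NAEK, transgenic cells differed from HEK293T cells in the transgenes and in few other regions past the threshold. Of 46156 coding regions 3 passed, both transgenes higher and ENST00000322002 lower, while 4541 had an unadjusted p under 0.05, against 2308 from chance. The latter had 20.6 ± 2.08 RPKM (SD, n = 2) in HEK293T and 3.42 ± 0.193 RPKM in transgenic cells (log2 -2.29, limma adjusted p = 0.00185) and passed under all 13 alternatives run. Of first extended regions, GFP39 was higher (log2 5.72, limma adjusted p = 0.000783) and ENST00000295920, with a region of 3 nt, had 3 and 2 reads in HEK293T and 0 in transgenic cells. Relative to its coding density, the first extended region of GFP39 stood at 3.64 ± 0.311% in transgenic and 11.4 ± 6.02% in HEK293T libraries (SD, n = 2). With 1 RPKM added to both regions the log2 difference was -2.14 and did not pass (limma adjusted p = 0.917). HEK293T cells should hold no GFP39, and their 7.14 and 15.66% rest on 18 and 19 extended and 54 and 26 coding reads. These ratios therefore do not measure passage of a stop codon in HEK293T cells. The share of first extended reads differed by -0.0265 percentage points, transgenic minus HEK293T (exact permutation p = 0.333, the smallest possible). In second extended regions, ENST00000496634 was lower, with 6 and 5 reads in HEK293T and 0 in transgenic cells (log2 -5.17, limma adjusted p = 0.00305). Coding calls numbered 23 with no filter, 71 with at least 50 reads in every library of 1 group and 345 under voom. First extended calls numbered 1 without HEK293T -NAEK replicate 2 or either transgenic -NAEK library, and second extended calls 0 without either HEK293T -NAEK library and 2 without transgenic -NAEK replicate 2.

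With NAEK, transgenic and HEK293T cells differed in first extended regions in both directions. Of 7801 regions, 111 were higher in transgenic cells, GFP39 included (log2 9.52, limma adjusted p = 2.12e-05), and 26 were lower. The balance turned to 11 higher and 16 lower with at least 50 reads in every library of 1 group and to 11 higher and 14 lower with a pseudocount of 0.1, and was 44 and 34 without transgenic +NAEK replicate 1. The 110 endogenous regions that were higher had a median length of 117 nt and the 26 lower ones 18.0 nt. ENST00000329421 had 9 and 7 reads in HEK293T and 171 and 190 in transgenic cells (log2 4.27, limma adjusted p = 0.0314), and ENST00000589520, with a region of 93 nt, had 1 and 1 against 58 and 31 reads (log2 4.31, limma adjusted p = 0.0314). ENST00000295920 and ENST00000399455, with regions of 3 and 6 nt, had 5 and 3 and 3 and 6 reads in HEK293T and 0 in transgenic cells. Such thin coverage does not hold for all lower regions. Over the 8 libraries, 17 of the 26 lower and 89 of the 110 higher regions held under 50 reads. The count of 137 was 1 without either HEK293T +NAEK library, 78 without transgenic +NAEK replicate 1, 14 without transgenic +NAEK replicate 2, 1 when only the 4 libraries compared were fitted, 2 with no read minimum and 350 under voom. GFP39's first extended density was 9.46 ± 0.615% of its coding density in HEK293T and 20.02 ± 1.301% in transgenic libraries (SD, n = 2), on a HEK293T level of 0.802 RPKM. HEK293T cells should hold no GFP39, and the ratio there rests on 12 and 8 extended reads. With 1 RPKM added to both regions the log2 difference of the ratios was 0.07 and did not pass (limma adjusted p = 0.973). First extended reads were 0.0176 percentage points higher in transgenic cells (exact permutation p = 0.333, the smallest possible), a value that ran from 0.0032 with at least 200 coding reads to 0.0388 without the 10 transcripts with the most reads, and was 0.1105 with the transgenes.

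Coding regions differed in 6 of 46156 transcripts between the lines with NAEK, both transgenes higher and 4 lower, while 7206 had an unadjusted p under 0.05, against 2308 from chance. ENST00000322002 had 19.96 ± 1.73 RPKM (SD, n = 2) in HEK293T and 3.83 ± 0.22 RPKM in transgenic cells (log2 -2.12, limma adjusted p = 0.00338). Over its 13 alternatives adjusted p ran from 6.55e-07 to 0.0743, the highest without HEK293T +NAEK replicate 2. ENST00000265191 had 33 and 23 reads in HEK293T and 1 and 0 in transgenic cells (log2 -1.69, limma adjusted p = 0.0468), and passed under 4 of 12 alternatives, but not without any 1 of the 4 libraries compared (adjusted p 0.164 to 0.308). The count was 2 without HEK293T +NAEK replicate 2, 513 with at least 50 reads in every library of 1 group and 931 under voom. In second extended regions 2 passed, GFP39 higher (log2 4.34, limma adjusted p = 0.0396) and ENST00000589468 lower, with 3 and 2 against 0 reads. That count was 0 without either HEK293T +NAEK library or without transgenic +NAEK replicate 2, 3 without transgenic +NAEK replicate 1 and 18 under voom.

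The interaction asked whether NAEK acted differently in the cell lines. By limma 0 coding regions passed (1764 at an unadjusted p under 0.05, 0 under voom), 0 first extended regions (679 and 22) and 1 second extended region (163 and 0). The one that passed was ENST00000496634, with a log2 difference of 5.25 (limma adjusted p = 0.0284). This region had 0 reads in transgenic cells without NAEK and similar densities in the other groups. It passed under 7 of 19 alternatives, and the count was 0 whichever of the 8 libraries was left out. Some first extended regions did pass by limma with at least 50 reads in every library of 1 group, or with at least 30 reads in the region. The NAEK difference in the share of first extended reads was 0.0441 percentage points larger in transgenic cells, and for second extended reads the value was -0.0114, with no test of either. The first ran from 0.0266 with at least 200 coding reads to 0.0716 without the 10 transcripts with the most reads, and was 0.136 with the transgenes. The second was -0.0025 without HEK293T +NAEK replicate 1, -0.0203 without HEK293T +NAEK replicate 2, -0.0071 without transgenic -NAEK replicate 2 and -0.0061 without transgenic +NAEK replicate 1.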

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

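All weighing tests in this part were chosen only after the results were seen.

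The NAEK effect on the first extended region of GFP39 stood out with a log2 difference of 3.80 between transgenic and HEK293T libraries. It was not past the threshold after adjustment (limma adjusted p = 0.114). HEK293T cells should hold no GFP39, and their libraries held 18, 19, 12 and 8 reads of the region. This difference therefore cannot compare how the lines respond. The NAEK effect on the second extended region of ENST00000496634 differed between the lines by 5.25 (limma adjusted p = 0.0284), on 0 to 10 reads per library. Only the transgenic libraries without NAEK had 0 reads. The HEK293T libraries, which should hold no transgene, together held 871 synthetase reads, 254, 223, 192 and 202 per library, a signal in entries outside the comparisons of endogenous transcripts.

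The synthetase reads in HEK293T libraries amounted to 0.169% of the transgenic level relative to library totals. Transgenic cells in the HEK293T cultures would bring the synthetase and GFP39 profile of their own NAEK state, but the first extended share of GFP39 reads was 31.6% without NAEK (95% interval 23.3 to 40.9%), against 14.5% in transgenic cells, and 30.8% with NAEK (19.9 to 43.5%), against 48.4%. Over the synthetase and both GFP39 regions the misfit was 14.7 times the spread between HEK293T replicates, and each library alone missed the profile at a simulated share of 0.0389 or lower with counting error only, which argues against such cells as the whole source. Reads assigned to the wrong library, in 1 mixture of the transgenic groups, gave 95.1 GFP39 coding and 68.2 first extended reads against 125 and 57 observed, at a simulated share of 0.001, but that gap rests on HEK293T -NAEK replicate 1, without which the share was 0.297. Misassigned reads stay open, and no biological explanation was tested.

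First extended regions that rose with NAEK in transgenic cells could reflect more ribosomes on the whole transcript, an effect of NAEK itself, or chance among thin regions. Coding regions of the 124 transcripts changed by a mean of 0.031 (log2, SE 0.013 over transcripts) against 2.65 in the extended regions. The same extended regions changed by -0.006 (SE 0.047 over transcripts) with NAEK in HEK293T cells, so both of the former are argued against as the whole cause. The 2.65 is inflated by choosing the regions on it, but among transcripts chosen on HEK293T libraries alone 76 reached 5% of coding density in both libraries with NAEK and 5 in both without it, or 146 and 148 against 39 and 48 in single libraries. In the 124 transcripts, pooled extended reads were 0.0541 and 0.0653% of coding reads without NAEK, under the 0.104 to 0.118% of HEK293T libraries, a gap that selection can give. As a hypothesis, the tRNA charged with NAEK may let ribosomes pass stop codons of endogenous transcripts, which stays untested because stop codons were not used here.

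GFP39 coding density was 1.78-fold higher with NAEK in transgenic cells, although limma did not call it. If reading through a stop codon raised density before it in every transcript, coding regions of transcripts with a raised extended region should move alike. Those of the 110 transcripts with more extended footprints in transgenic than HEK293T cells with NAEK changed by a mean of 0.042 (log2, SE 0.014 over transcripts), against 0.83 for GFP39. This argues against a general effect over whole coding regions. GFP39's coding region came out as 144 nt, against a median of 1137 nt over coding regions with at least 200 reads. An effect near the stop codon alone would be diluted in longer regions, so the values cannot decide on it. A change in GFP39 mRNA level or stability may remain, and was not tested because mRNA was not analysed here.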

How the results depend on the processing

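Results were recomputed under 1024 alternatives over 78 results, of which voom, no variance trend, the log2 ratio to coding regions, the 30-read minimum, the subsets of transcripts and the counts of transcripts chosen on HEK293T libraries were chosen after seeing the data. Of counts and shares that answer a comparison, 232 stayed within the spread between replicates (1 SD) or, for counts, within 1.5 times, 138 moved and 3 reversed, while 10 shares under the replicate block could not move. Among those that stayed, the LP share of second extended reads defined below turned from -0.0062 to 0.0027 without HEK293T +NAEK replicate 1. Of single regions named, together with the set tests under the estimated correlation, 468 kept direction and side of the threshold, 163 fell short of it, 8 passed newly and 2 reversed. Among simulated first extended regions limma called 3% of 2-fold and 38% of 8-fold changes, so most changes of either size are out of reach at this depth. Where a setting changes the regions tested or the libraries fitted, the count moves by construction with them, and otherwise the cause was not tested. A lone sample left in an arm was assumed to vary like the other groups. Below, TN is the NAEK effect in transgenic cells, HN in HEK293T cells, LM and LP the difference of lines without and with NAEK, and IX the interaction.

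For the share of first extended reads (percentage points), at least 20 coding reads gave TN 0.0921, LP 0.0318 and IX 0.0632. At least 200 gave TN 0.0631, HN 0.0365, LP 0.0032 and IX 0.0266. Without the 10 transcripts with the most reads, HN was 0.0002, LP 0.0388 and IX 0.0716. Protein-coding transcripts gave HN 0.0421, LP 0.0038 and IX 0.0344. Those with an extended density under 10% of coding density gave TN 0.0607, HN -0.0002, a reversal, LP 0.0381 and IX 0.0609. With the transgenes, TN was 0.168, LP 0.1105 and IX 0.136. Leaving out 1 library gave TN 0.0686 to 0.0829, HN 0.0282 to 0.0350, LM -0.0336 to -0.0194, LP 0.0146 to 0.0206 and IX 0.0370 to 0.0512. For second extended reads, TN was 0.0019 without the 10 transcripts, and LM reversed to -0.0042 in protein-coding transcripts and -0.0012 with the transgenes. Leaving out 1 library gave TN 0.0040 to 0.0145, HN 0.0118 to 0.0295, LM 0.0009 to 0.0096, LP -0.0150 to 0.0027 and IX -0.0203 to -0.0025.

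For coding counts, no filter gave TN 1, HN 1, LM 23 and LP 3. At least 50 reads in every library of 1 group gave HN 1, LM 71 and LP 513. Voom gave TN 9, HN 1, LM 345 and LP 931. Leaving out 1 library gave LM 3 to 4 and LP 2 to 6. For first extended counts, no filter gave TN 0, LM 1 and LP 2. At least 50 reads gave TN 11, LM 1, LP 27 and IX 8. At least 30 in the region gave LM 1 and IX 17. Pseudocounts of 0.1 and 5 gave TN 21 and 226 and LP 25 and 257. The 4 compared libraries gave TN 0, LM 0 and LP 1. The ratio to coding gave TN 1, LM 1 and LP 14. Without the 10 transcripts LM was 1. Voom gave TN 274, HN 2, LM 1, LP 350 and IX 22. No variance trend gave TN 76 and LP 63. Leaving out 1 library gave TN 0 to 40, LM 1 to 2 and LP 1 to 78. For second extended counts, no filter gave LM 2, LP 0 and IX 0. At least 50 reads gave LM 0 and IX 0. At least 30 gave TN 1 and LM 2. At least 20 coding reads gave LP 0, and at least 200 gave TN 0, LM 0 and IX 0. A pseudocount of 0.1 gave TN 4, HN 3, LM 3, LP 11 and IX 4, and 5 gave TN 1, LP 0 and IX 0. The 4 compared libraries gave TN 0, LM 0 and LP 0. The ratio gave LM 2. Voom gave TN 0, LM 3, LP 18 and IX 0. No variance trend gave LM 2 and IX 2. Leaving out 1 library gave TN 1 to 6, LM 0 to 2, LP 0 to 3 and IX 0.

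The log2 ratio to the coding region, with 1 RPKM added to both, turned GFP39's first extended region in LM to -2.14. That rests on 11.4% of coding density in HEK293T libraries, which should hold no GFP39, and 3.64% in transgenic ones. For the second extended region of GFP39 in LP the same ratio gave -5.11. Its sign was set by the added 1 RPKM, since the region held 0 reads in HEK293T cells and stood at 0.295% of coding density in transgenic cells. Of transcripts chosen on HEK293T libraries, 31 with and 0 without NAEK reached 10% in both libraries (58 and 55 against 13 and 15 in single ones), 164 and 18 reached 5% in both with at least 500 coding reads, and 43 and 4 did so among those under 1% in HEK293T. With 1 library in place of 2, 146 to 148 and 39 to 48 reached it. Replicate agreement was 0.992 with at least 50 reads in every library.

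Replicate numbers were not taken as pairing, since labels tie no samples across groups. Deviations of same-numbered libraries correlated at 0.048 to 0.324 in coding and 0.012 to 0.084 in first extended regions. With the replicate number as a block, coding counts were 7 (TN), 6 (LM) and 263 (LP), first extended counts 0 (TN), 1 (LM) and 2 (LP), and second extended counts 0 (LP and IX). Differences of shares are fixed under that block, since each group has 1 library of each number.

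Of count-based tools only voom was run, on recovered reads, because values are RPKM. Not run were results by stop codon, upstream of the start codon and along the coding region, the share without 15 nt next to the stop codon, 1 feature per gene, and gene lists. The median share over transcripts was 0 in each library.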

Other observations

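The set tests and length classes in this part were chosen only after the results were seen, and 10 set tests and 5 length classes were run. The set tests included the 124 transcripts in the contrast that chose them, an outcome fixed in advance. Its place in the Benjamini-Hochberg adjustment makes the adjusted camera p of 0.057 below lower than it would be without that test.

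Second extended regions of the 124 transcripts whose first extended region rose with NAEK were higher with NAEK in transgenic cells by a mean log2 of 0.410 (SE 0.071), against 0.026 in other transcripts. Of these, 55 were higher, 6 lower and 63 at no change, so that the median was 0. The camera p was 9.55e-05 with the preset correlation and 0.0171 with the estimated correlation, or 0.057 after Benjamini-Hochberg over the 10 tests, so the call is lost there. The 124 transcripts were chosen on the same transgenic libraries, so these p-values are not independent of that choice. In HEK293T cells the mean was 0.060 (SE 0.037), with p = 0.457 at the estimated correlation, and the difference between cell lines was not tested.

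First extended regions of 3 to 6 nt on 234 transcripts held 0.401 ± 0.018% of coding reads in HEK293T and 0.281 ± 0.0153% in transgenic libraries (SD, n = 4 each; exact two-sided permutation p = 0.0286, the smallest possible, and 0.143 after Benjamini-Hochberg over the 5 classes). All 4 transgenic libraries lay below all 4 HEK293T libraries, where libraries without and with NAEK were pooled in each line. The transgenic level was 0.70 times that of HEK293T in this class and 0.809 times at 7 to 12 nt. It was 0.921 times at 13 to 60 nt, 0.984 times at 61 to 240 nt and 1.087 times over 240 nt. These other classes had exact permutation p from 0.0571 to 0.857, so the class of 3 to 6 nt had the lowest p of the 5. That rank was not particular to it. Without the 10 transcripts with the most reads in each class, the class of 13 to 60 nt had the same exact permutation p of 0.0286. It then held 0.557% in HEK293T and 0.485% in transgenic libraries. Over the 26 first extended regions that were lower in transgenic cells with NAEK, 21 were also lower without NAEK and 5 higher, with a mean log2 of -0.869 (SE 0.296) and a camera p of 0.0121 at the estimated correlation, 0.057 after adjustment. The cause was not tested.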
